A study of Mus musculus with 27 samples.

How the data were processed

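Polyadenylated RNA of sorted alveolar macrophages was sequenced as 27 libraries in 9 groups of 3, resident cells on days 0, 3, 6, 9 and 12 and recruited cells on days 3, 6, 9 and 12. Per the labels, LPS was given into the trachea as 20 ng in 50 µL of saline, a mass unit that could not be checked here, libraries were made with a modified stranded mRNA kit, and barcoded pools were run on an Ion Proton. The unit of the deposited table is the raw read count per Ensembl gene, 1 column per library, without normalization. The submitters' processing notes list STAR 2.4.0a, HTSeq 0.6.0, DESeq2 1.4.5, R 3.1.0 and the genome build mm10, without roles. The strand option and the annotation release are not given in the sources used here. A second deposited table holds the counts of reads that were not assigned to a gene, in 5 classes, and it stayed out of library sizes and tests. Reads outside any gene were 6.77% to 26.5% of the reads assigned to a gene, to several genes or to none (median 9.70%, and 9.16% to 11.2% in untreated cells), and ambiguous reads 1.01% to 1.66%. All 27 count columns were used.

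The count table had 38124 genes, of which 36345 had a symbol in GENCODE mouse release M21, and genomic positions came from that release. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 13599. Totals were 11093216 to 18299674 counts per library, and 16152 to 17621 genes had a count. With 3 libraries against 3, an exact permutation test cannot go below p = 0.1, so single genes were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, 1 mean per group over all 27 libraries (18 residual degrees of freedom), robust dispersions, the quasi-likelihood F test, which is two-sided for single contrasts, and Benjamini-Hochberg adjustment with a threshold of 0.05. Changes are log2 ratios with a standard error from the F statistic. The 16 comparisons were recruited against resident cells averaged over days and on each day, resident cells on each and on any day against day 0, recruited cells on each and on any later day against day 3, and the change of the population difference over days. Mean levels are CPM, the counts of a gene scaled to the library total with TMM factors, and plotted log2 CPM used a prior count of 2. Comparisons of resident days share the day 0 libraries, and those of recruited days share day 3.

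Gene lists, 29 in number, were written before the data were examined, as were the groups, the tests, most of the alternatives and the rule for naming genes. They covered resident identity, classical monocytes, monocyte-derived macrophages, inflammatory mediators, interferon-stimulated genes, the cell cycle, glycolysis, the citrate cycle, oxidative phosphorylation, fatty acid oxidation, lipid handling, cholesterol synthesis, arginine and polyamines, repair and matrix, antigen presentation, apoptosis, efferocytosis, pattern recognition, immediate early and heat shock genes, markers of neutrophils, T and NK cells, B cells, dendritic cells, eosinophils and basophils, epithelium, red cells, endothelium and stroma, sex genes and the sort markers. Lists with at least 5 tested genes were tested with limma 3.58.1 by camera, with a preset correlation between genes of 0.01 and with an estimated one, and by fry. List scores are means of log2 CPM, tested by 1e+05 permutations within days.

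Genes were named by rule. From each list, up to 4 genes with adjusted p under 0.05 and no overlap between the libraries of the compared groups, which chance gives in 10% of genes for 3 against 3, were taken by size of change. For the average over days, the groups had to be apart on each day in the same direction. The interaction had no rule on overlap. Added were the 5 most raised and 5 most lowered genes with a mean of at least 20 CPM in the higher group, and a fixed set of marker genes. Genes named as exceptions within a list were picked after their values were seen. Where a group had no count, the ratio was computed against a floor of 3 counts over the group. With 1 to 3 counts, the 95% counting interval is given. Such floors and intervals cover counting error only. Reads shared between near-identical genes (the globins, Ly6c1 and Ly6c2, the heat shock 70 pair, histocompatibility genes) were not separated further.

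Whether equal replicate numbers mark shared material was checked from the data. The deviations from the group means correlated in all 12 resident and recruited pairs of the same day and number (r from 0.17 to 0.52, across genes), and each of the 12 libraries of either population correlated best with its own number on that day. The pairing thus comes from the data and not from the labels, and a fit with 1 block per day and number is given where it changes a call. Columns of the unassigned-read table carry numbers in front of the group names, whose meaning is not given in the sources used here. After these numbers were seen, they were grouped by eye into 4 runs, 2 to 9, 12 to 18, 19 to 28 and 34 to 53. There is no gap between 18 and 19, where the order of groups starts over, and 34 stands apart but was kept with 48 to 53. The resident and the recruited library of each of the 12 pairs fell in the same run. Shared material and a shared run thus cannot be told apart as the source of the pairing. The run was used as a covariate and is given beside each comparison. Within runs that held both groups, 95.2% to 100% of the called genes had the same direction, on the libraries they were called from.

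Alternatives set in advance were RLE scaling, library size alone, no filter and a stricter filter (at least 1 CPM in 12 libraries), DESeq2 1.42.0, replicate number as a block, the block within days, only the libraries of the compared groups, each library left out in turn and a prior count of 0.5. Chosen after seeing the data were the number run as covariate, the 4 libraries numbered 12 to 18 left out, set tests with both the block within days and an estimated correlation, and the day 6 pair with the highest share of reads outside genes left out. Counts were simulated with the same groups, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold, none from the lowest quartile of mean level. All other genes had the same mean in all libraries, whereas 46.6% of the real genes were called between the populations on day 3. The shares recovered hold for that setting and may not hold for the real counts. Between the populations on day 3, the fit recovered 35.8%, 71.6% and 92.4% of these genes, with 3.62% false calls. For resident day 12 against day 0 the shares were 43.3%, 76.1% and 95.5%. For the average over days they were 85.1%, 92.5% and 98.5%, for the interaction of day 12 against day 3 10.4%, 49.3% and 83.3%, and for resident cells on any day 32.8%, 76.1% and 93.9%.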

Results

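Messenger RNA was counted gene by gene in alveolar macrophages washed from the lungs of C57B/6 mice by bronchoalveolar lavage and sorted by surface markers. Intratracheal lipopolysaccharide (LPS), a bacterial cell wall component, had been given to cause acute lung injury. Resident macrophages (CD11c positive, CD11b negative) came from untreated mice (day 0) and from days 3, 6, 9 and 12 after LPS, and recruited macrophages (CD11c negative, CD11b positive) from days 3, 6, 9 and 12. Each of the 9 groups had n = 3 libraries, 27 in all, with 11093216 to 18299674 counts per library (median 14859352). The labels do not say whether the libraries of a group come from separate animals, and if they do not, the p-values below measure only the spread between these samples. The series title asks how cell origin and later programming set resident and recruited macrophages apart during lung injury. Genes marking the populations and the response were, in GRCm38 coordinates, Siglecf (ENSMUSG00000039013, chromosome 7, 43351341 to 43359531), C1qa (ENSMUSG00000036887, chromosome 4, 136895917 to 136898803), Nos2 (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484) and Mmp14 (ENSMUSG00000000957, chromosome 14, 54431612 to 54445364), each annotated as protein coding.

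Population and day set the libraries apart. The first principal component held 72.7% of the variance of the 1000 most variable genes and separated recruited from resident cells. The next held 13.2% and separated day 3 from all other days in both populations.

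**Figure D1:**
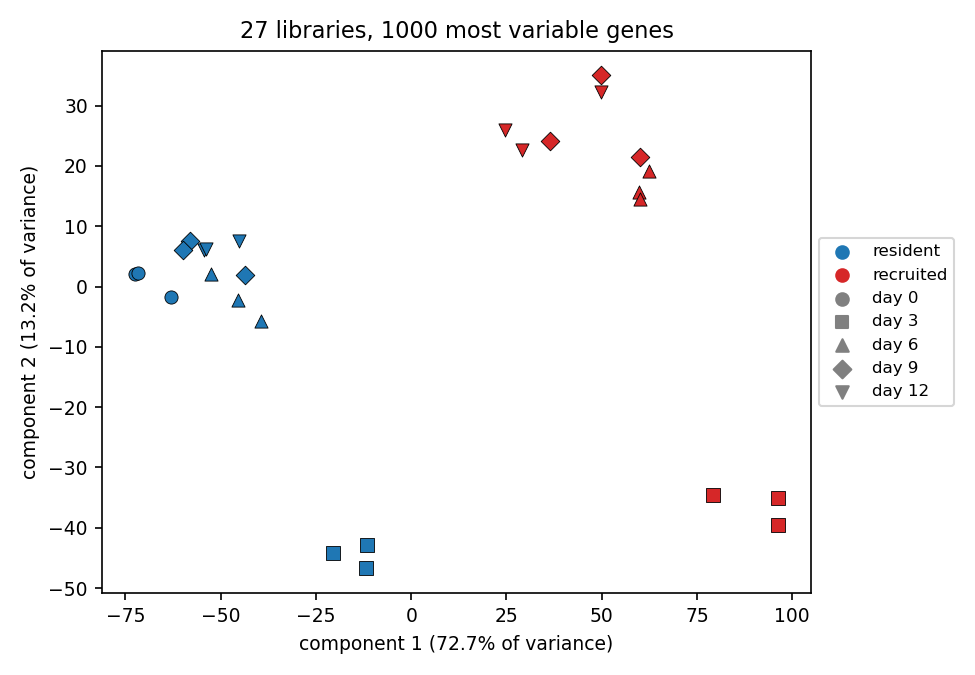
First and second principal component of the 27 libraries (72.7% and 13.2% of the variance of log2 CPM over 1000 genes), 1 point per library, colour for the population and shape for the day. Recruited libraries lie to the right and day 3 libraries at the bottom.

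Recruited cells were compared with resident cells averaged over days 3, 6, 9 and 12. The populations are defined here by surface markers, so this comparison cannot tell cell origin apart from cell state. Recruited cells were lower in the genes that mark lung-resident macrophages: of 30 tested, 26 were lower and 2, Bhlhe40 (0.29) and Gpnmb (1.71), were higher on the log2 scale (29 passed when adjusted over the list alone). Siglecf, a sialic acid receptor of alveolar macrophages, differed by -4.20 ± 0.33 log2 (SE, 12 libraries per population, adjusted p = 6.88e-10). Cidec, a lipid droplet protein, differed by -4.68 ± 0.41 (adjusted p = 4.67e-09), and Pparg, the nuclear receptor that directs alveolar macrophage development, by -1.80 ± 0.16 (adjusted p = 4.97e-09). Genes of classical monocytes were higher in recruited cells, 17 of 20 tested against 1 lower, Lyz2 at -0.35 (18 adjusted over the list alone), with Ly6c2, which cannot be fully told from its paralog Ly6c1, at 6.12 ± 0.37 (adjusted p = 1.57e-11) and F13a1, a clotting factor subunit, at 6.35 ± 0.39 (adjusted p = 2.53e-11). Genes of newly differentiated tissue macrophages were higher in 22 of 24 tested and lower in 2, Mertk (-0.75) and Cd81 (-2.71) (24 adjusted over the list alone). Among them, Apoe, a lipid carrier, was higher by 6.37 ± 0.34 (adjusted p = 1.52e-12) and the complement gene C1qa by 6.79 ± 0.72 (adjusted p = 8.11e-08, and 7.47 log2 without resident day 12 replicate 1).

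Cell division and metabolism genes also differed between the populations. All 45 of 45 tested cell cycle genes were lower in recruited cells (45 adjusted over the list alone), with the mitotic motor Kif23 at -2.85 ± 0.18 (adjusted p = 6.94e-12) and the proliferation marker Mki67 at -0.96 ± 0.20 (adjusted p = 0.00029). Fatty acid oxidation genes were lower in 23 of 25 tested and higher in 2, Echs1 (0.29) and Acsl1 (0.36) (25 adjusted over the list alone), and the peroxisomal enzyme Ehhadh differed by -3.39 ± 0.16 (adjusted p = 6.58e-14). Glycolysis genes were higher in 15 of 22 tested and lower in 3, Pfkp (-0.21), Pfkfb4 (-1.52) and Aldoc (-1.81) (18 adjusted over the list alone), with the muscle-type phosphofructokinase gene Pfkm at 1.58 ± 0.14. Citrate cycle genes were lower in 18 of 22 tested, with Sdhb higher at 0.15 (19 adjusted over the list alone), and cholesterol synthesis genes were lower in 18 of 22 and higher in none (18 adjusted over the list alone). Of 45 tested oxidative phosphorylation genes, 6 were higher and 17 lower (23 adjusted over the list alone). Of 26 lipid handling genes, 7 were higher and 14 lower (21 adjusted over the list alone). Of 16 arginine and polyamine genes, 9 were higher and 4, Oat, Srm, Amd1 and Sat1, lower (13 adjusted over the list alone). Nos2 and Arg1, which turn arginine into nitric oxide and into ornithine, were both higher in recruited cells, by 5.20 ± 0.33 (adjusted p = 8.07e-11) and 5.67 ± 0.73 (adjusted p = 1.23e-06).

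Genes of the inflammatory, interferon and repair lists were mostly higher in recruited cells, and related lists were more mixed. Of 29 tested inflammatory mediators, 17 were higher and 2, Ccl17 (-1.35) and Ccl22 (-1.18), lower (20 adjusted over the list alone). The monocyte attractant Ccl2 was higher by 5.42 ± 0.40 (adjusted p = 3.54e-10) and the growth factor Csf1 by 4.19 ± 0.19 (adjusted p = 8.16e-14), whereas Tnf was not called (0.59 ± 0.32, adjusted p = 0.117). It was called without recruited day 12 replicate 1 (0.0418) or replicate 2 (0.0479), within a range over the alternatives of 0.0418 to 0.692. Of 29 interferon-stimulated genes, 20 were higher and none lower (20 adjusted over the list alone). Repair and matrix genes were higher in 14 of 25 tested and lower in 5, Pdgfc, Cd9, Tgfbr1, Tgfbr2 and Ereg (19 adjusted over the list alone), with the vessel growth factor Vegfa at 6.58 ± 0.38 (adjusted p = 7.23e-12). Antigen presentation genes were higher in 9 of 17 and lower in 5 (15 adjusted over the list alone). Apoptosis genes were higher in 14 of 30 and lower in 5 (19 adjusted over the list alone), with the survival gene Bcl2 at 4.20 ± 0.17 (adjusted p = 1.95e-15). Efferocytosis genes, for clearing dead cells, were higher in 9 of 16 and lower in 4, Axl, Pros1, Calr and Rac1 (13 adjusted over the list alone). Pattern recognition genes were higher in 14 of 31 and lower in 8 (22 adjusted over the list alone), and immediate early and heat shock genes were higher in 6 of 17 and lower in 1, Egr2 (6 adjusted over the list alone).

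Markers of other cells differed in part between the populations. Those of T and NK cells were higher in 14 of 16 tested and lower in none (14 adjusted over the list alone), with Il7r at 4.23 ± 0.36. Neutrophil markers were higher in 4 of 14 and lower in 2 (6 adjusted over the list alone), dendritic cell markers higher in 4 of 12 and lower in 3 (7 adjusted over the list alone), and endothelial and stromal markers higher in 4 of 5 and lower in 1 (5 adjusted over the list alone). Epithelial markers were higher in 1 of 11, Ager, and lower in 3, Epcam, Cdh1 and Foxj1 (3 adjusted over the list alone), and their median of 0.73 and mean of 0.2 differed in sign from the set test, which pointed down (adjusted p = 0.824). The B cell list had 2 tested genes with 1 higher, Ighm, the erythroid list 4 tested genes with none called by edgeR, 0 at an unadjusted p under 0.05 and 0 by DESeq2, and the sex gene list 4 tested genes with 1 higher, Eif2s3y, while no eosinophil or basophil marker passed the count filter. Itgam and Itgax encode the surface proteins of the sort gate and were not read as findings between populations. Over time, Itgax of recruited cells rose from day 3 by 1.53 log2 on day 9 and by 2.58 on day 12, in cells gated as CD11c negative. Whether the gate was the same on all days is not given in the sources used here.

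In total, 8198 of 13599 tested genes differed between the populations, 4120 higher and 4078 lower in recruited cells (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). A fit with the run of library numbers as a covariate called 8751. Camera's set test with a preset correlation called the resident identity (adjusted p = 1.94e-11, and adjusted p = 0.155 with an estimated correlation) and cell cycle lists (adjusted p = 4.81e-16, and adjusted p = 0.3 with an estimated correlation). Over all comparisons it called 140 of 312 set tests, of which 8 held with an estimated correlation, and each of the 8 is named below. Repair and matrix genes passed the set test with the preset correlation and pairs of libraries as a block (adjusted p = 0.0584 without and 0.0133 with the block), as did immediate early genes (0.108 without and 0.0133 with it). Neither passed with the block and an estimated correlation (0.183 and 0.421). Without the block, camera with the preset correlation did not call apoptosis (adjusted p = 0.0584), antigen presentation (0.131), pattern recognition (0.131) or efferocytosis genes (0.321). With the block it did not call them either (0.0551, 0.149, 0.101 and 0.106). The mean score of the resident identity genes differed by -2.88 (recruited minus resident), with a permutation p of 1e-05 within days, the smallest that the permutations can give. Labels were permuted freely within days. Swaps within the pairs of libraries alone would not allow so small a p.

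**Figure D2:**
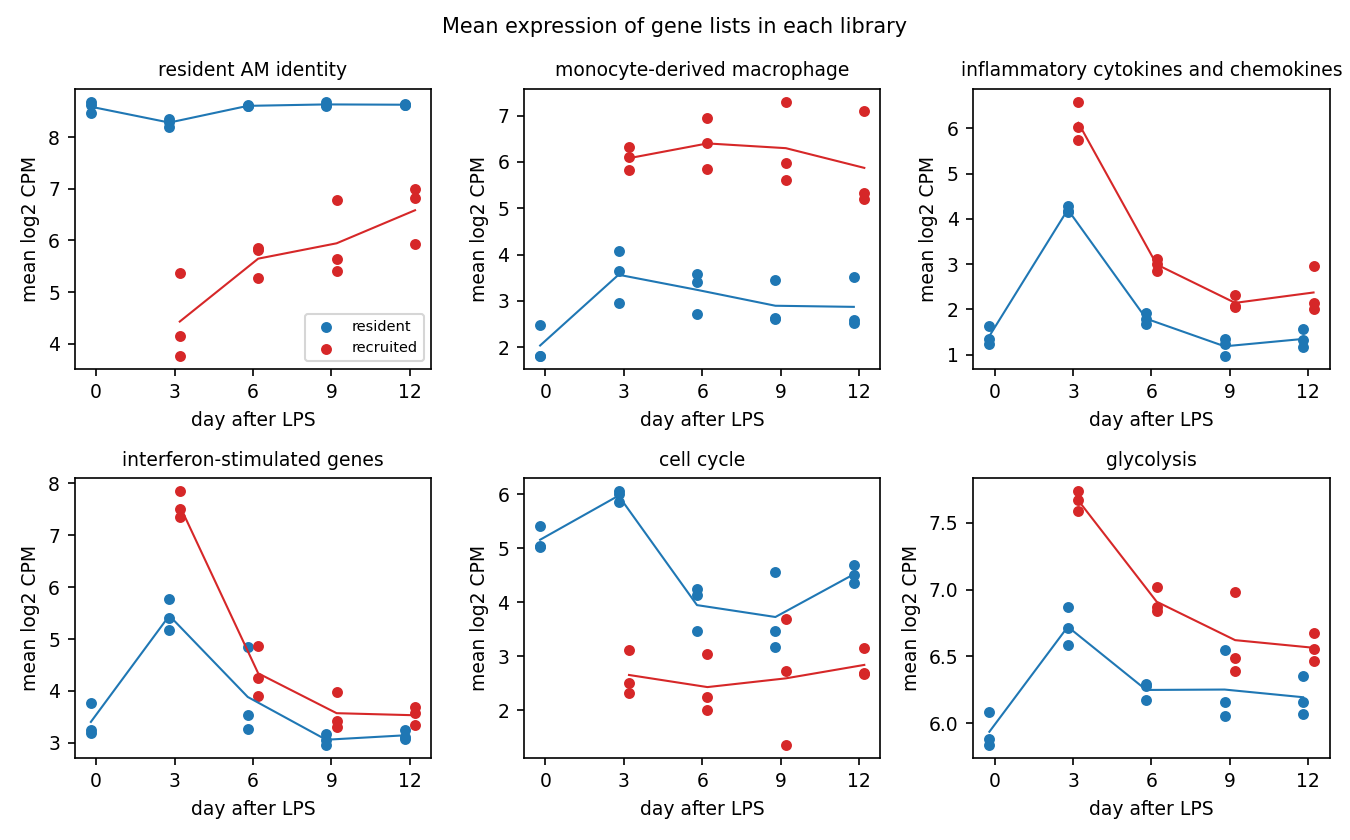
Mean log2 CPM of 6 gene lists against the day after LPS, 1 point per library and a line through the group means, resident in blue and recruited in red. Resident identity genes were higher in recruited cells on day 12 than on day 3, and interferon-stimulated and inflammatory genes were highest on day 3 in both populations.

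The same comparison on single days asked when the populations were furthest apart. On day 3, all 29 of 29 interferon-stimulated genes were higher in recruited cells (29 adjusted over the list alone), with Ifi44 at 4.69 ± 0.47 (SE, n = 3 per group), and so were 19 of 29 inflammatory mediators with 1 lower, Ccl17 at -4.02 (20 adjusted over the list alone). Mean Il1b, an inflammasome product, was 1370 ± 381 CPM (SD, n = 3) in recruited cells and 242 ± 12.7 in resident cells, a difference of 2.50 ± 0.53 log2 (SE, adjusted p = 0.000585). All 45 cell cycle genes were lower (45 adjusted over the list alone), with Kif23 at -4.51 ± 0.38 (adjusted p = 5.39e-09), and 26 of 30 resident identity genes were lower with none higher (27 adjusted over the list alone), with Siglecf at -5.16 ± 0.69 (adjusted p = 4.66e-06). Nos2 was higher by 4.83 ± 0.41 (adjusted p = 2.16e-08). Antigen presentation genes were higher in 11 of 17 with 1 lower, Icosl (13 adjusted over the list alone), with the costimulator Cd86 at 3.86 ± 0.29. Of 13599 genes, 6342 differed, 3149 higher and 3193 lower, and with library size alone as scaling the split was 2302 to 3668 with the median of all genes moved by -0.12. The fit with the number run called 7159. Ifi44 differed by 5.37 without resident replicate 1 and Siglecf by -6.53 without recruited replicate 1. With the block, the set tests of repair (0.106 to 0.0335), immediate early (0.0863 to 0.0041) and neutrophil genes (0.0863 to 0.0212) passed with the preset correlation but not with an estimated one (0.196, 0.314 and 0.314).

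On day 6, repair and matrix genes were higher in 11 of 25 tested and lower in 5, Pdgfc, Cd9, Tgfbr1, Tgfbr2 and Ereg (18 adjusted over the list alone). Vegfa was higher by 7.34 ± 0.73 log2 (SE, n = 3 per group, adjusted p = 1.8e-07) and Pdgfa, a platelet-derived growth factor gene, by 6.90 ± 0.67. Thbs1, of the classical monocyte list, was higher by 7.02 ± 0.95. Mean Apoe was 14400 ± 2910 CPM (SD, n = 3) in recruited and 134 ± 76.8 in resident cells (6.74 ± 0.69 log2, adjusted p = 2.02e-07). Monocyte-derived macrophage genes were higher in 18 of 24 and lower in 2, Mertk (-0.80) and Cd81 (-2.74) (21 adjusted over the list alone). Interferon-stimulated genes were split, with 4 of 29 higher, among them Ifi44 at 3.82, and 4 lower, among them Stat2 at -0.47 (5 adjusted over the list alone). Cell cycle genes were lower in 34 of 45 and higher in none (39 adjusted over the list alone), whereas Mki67 was not called (-0.46 ± 0.39, adjusted p = 0.398) except with the block of library pairs (0.0393, in a range of 0.0393 to 0.622 over the alternatives). Vegfa differed by 8.17 without resident replicate 1 and by 6.68 without recruited replicate 1, and Ifi44 by 3.20 without the latter. In total 4758 genes differed, 2208 higher and 2550 lower, and 5695 with the number run as covariate. With the block, the set tests of repair (0.113 to 0.0336) and immediate early genes (0.163 to 0.025) passed with the preset correlation but not with an estimated one (0.298 and 0.509).

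On day 9, resident identity genes were lower in 26 of 30 and higher in 1, Gpnmb at 2.55 (27 adjusted over the list alone), with Siglecf at -3.90 ± 0.64 log2 (SE, n = 3 per group, adjusted p = 7.45e-05). Monocyte-derived macrophage genes were higher in 20 of 24 and lower in 2, Mertk (-0.79) and Cd81 (-2.54) (24 adjusted over the list alone). Among them, C1qa was higher by 8.02 ± 1.52 (adjusted p = 0.000376). The scavenger receptor Stab1, outside that list, was higher by 7.44 ± 0.92. C1qa was at 155, 1530 and 227 CPM in recruited replicates 1, 2 and 3. Csf1 was higher by 5.62 ± 0.43 (adjusted p = 3.49e-09). Resident cells had 2 Nos2 counts in all on this day, and recruited cells were 73.6-fold higher with a counting interval of 20 to 614. Cell cycle genes were lower in 15 of 45 and higher in none (18 adjusted over the list alone). Il1b was not called (-0.06 ± 0.51, adjusted p = 0.946). Without recruited replicate 2, C1qa differed by 6.29 and Stab1 by 6.23, and without resident replicate 2 by 9.51 and 8.37. Siglecf differed by -4.81 without recruited replicate 3. In total 4350 genes differed, 2114 higher and 2236 lower, 5331 with the number run as covariate, and 2497 when only these 6 libraries were fitted. With the block, the set tests of cholesterol synthesis (0.103 to 0.00761) and repair genes (0.0863 to 0.011) passed with the preset correlation but not with an estimated one (0.691 and 0.293).

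On day 12, the populations were still apart in 3713 genes, 1716 higher and 1997 lower in recruited cells, and in 4661 with the number run as covariate. Resident identity genes were lower in 23 of 30 and higher in 1, Gpnmb at 2.13 (27 adjusted over the list alone), with Siglecf at -3.07 ± 0.61 log2 (SE, n = 3 per group, adjusted p = 0.000782), while Pparg was not called (-0.83 ± 0.32, adjusted p = 0.0571) except with the number run, with only these 6 libraries, with the block of pairs and with DESeq2 (0.00514, 0.0326, 0.00495 and 0.0387, in a range of 0.00495 to 0.24 over the alternatives). Stab1 was higher by 7.65 ± 1.01 (adjusted p = 1.27e-05) and Bcl2 by 4.58 ± 0.34 (adjusted p = 3.47e-09). Stab1 was higher by 6.85 without recruited replicate 1. Cell cycle genes were lower in 40 of 45 and higher in none (45 adjusted over the list alone). Repair and matrix genes were higher in 10 of 25 and lower in 3, Cd9, Tgfbr2 and Ereg (13 adjusted over the list alone), and none of the 22 cholesterol synthesis genes was called by edgeR (0 adjusted over the list alone, 0 at an unadjusted p under 0.05 and 0 by DESeq2). With the block, the set tests of arginine (0.108 to 0.0435), efferocytosis (0.194 to 0.0393) and immediate early genes (0.187 to 0.0225) passed with the preset correlation but not with an estimated one (0.361, 0.361 and 0.519).

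The response of resident cells was measured against untreated resident cells. No group was given saline alone, so effects of LPS and of the instillation cannot be told apart. On day 3, inflammatory mediators rose in 20 of 29 tested and fell in none (22 adjusted over the list alone), and their set test passed (adjusted p = 1.46e-11, and adjusted p = 0.0402 with an estimated correlation). Il1b rose from 11.8 ± 4.09 to 242 ± 12.7 CPM (SD, n = 3), by 4.36 ± 0.58 log2 (SE, adjusted p = 2.49e-05), and the neutrophil attractant Cxcl3 by 6.31 ± 0.59 (adjusted p = 2.33e-07). Interferon-stimulated genes rose in 26 of 29 and fell in none (29 adjusted over the list alone), with the guanylate binding protein gene Gbp3 at 3.85 ± 0.24 (adjusted p = 1.52e-10). No Nos2 count was seen on day 0, and its day 3 level was at least 1270-fold higher. The metalloprotease gene Mmp14 rose by 7.11 ± 0.66 (adjusted p = 1.81e-07, and by 7.83 without day 0 replicate 1, as Cxcl3 did by 6.93), and Ass1, which rebuilds arginine, by 5.79 ± 0.37 (adjusted p = 5.06e-10). Monocyte genes rose in 11 of 20 and fell in 1, Itga4 at -0.61 (15 adjusted over the list alone), with Ly6c2 at 9.00 ± 1.03 (adjusted p = 3.53e-06). Its day 0 counts were all in replicate 3, and its rise came to 3.44% of the gap between day 0 and recruited day 3 cells. Monocyte-derived macrophage genes rose in 6 of 24 and fell in 1, Mertk at -0.54 (9 adjusted over the list alone). The rise of C1qa came to 2.18% of that gap.

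Part of the division and energy genes rose on day 3 as well. Cell cycle genes rose in 11 of 45 and fell in none (13 adjusted over the list alone), with cyclin E gene Ccne1 at 1.37 ± 0.35 log2 (SE, n = 3 per group). Glycolysis genes rose in 13 of 22 with a fall in 1, Pfkfb4 at -0.45 (16 adjusted over the list alone), oxidative phosphorylation genes in 22 of 45 with none lower (27 adjusted over the list alone) and citrate cycle genes in 10 of 22 with none lower (10 adjusted over the list alone). Arginine genes rose in 9 of 16 and fell in 1, Sat1 at -1.23 (10 adjusted over the list alone). Resident identity genes fell in 5 of 30, among them Bhlhe40 at -0.84 ± 0.16, and rose in none (5 adjusted over the list alone). Siglecf was not called (-1.18 ± 0.57, adjusted p = 0.141) except with only these 6 libraries fitted (0.0105, in a range of 0.0105 to 0.35 over the alternatives). Cxcr1, a chemokine receptor, fell by 3.68 ± 0.41 and the iron exporter Slc40a1 by 3.47 ± 0.48 (by 2.98 and 2.87 without day 0 replicate 1). Neutrophil markers rose in 9 of 14 (11 adjusted over the list alone), with Lcn2 at 12.23 ± 1.18 (adjusted p = 4.08e-07, and 13.01 log2 without day 0 replicate 2). T and NK cell markers rose in 6 of 16 (10 adjusted over the list alone), and Itgam, whose protein was gated against, rose by 5.84 ± 0.62. In total 3232 genes changed, 1802 up and 1430 down, and 1427 up and 1626 down with library size alone as scaling. The count was 4462 with the number run as covariate. Without resident day 3 replicate 3 the count was 1895.

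On day 6, cell cycle genes of resident cells had turned below the untreated level, with falls in 16 of 45 and rises in none (32 adjusted over the list alone), as in the helicase gene Mcm2 at -1.59 ± 0.22 log2 (SE, n = 3 per group). Their set test passed (adjusted p = 5.43e-35, and adjusted p = 0.39 with an estimated correlation). Mmp14 was higher by 6.00 ± 0.63 (adjusted p = 8.1e-06, and by 6.72 without day 0 replicate 1), the actin regulator Fmnl2 by 6.43 ± 0.33 (adjusted p = 2.13e-11) and Ass1 by 4.09 ± 0.37. Il1b was still raised (3.12 ± 0.56, and 2.43 without day 6 replicate 3), but only 4 of 29 inflammatory mediators were higher, Il1b, Ccl9, Cxcl3 and Cxcl16, and 1 was lower, Cxcl10 at -2.09 (5 adjusted over the list alone). Monocyte genes were higher in 6 of 20 (12 adjusted over the list alone), interferon-stimulated genes in 6 of 29 (10 adjusted over the list alone) and T and NK cell markers in 7 of 16 (11 adjusted over the list alone), with none of them lower. Siglecf was not called (0.19 ± 0.56, adjusted p = 0.91). In total 873 genes changed, 513 up and 360 down, and 371 up and 630 down with library size alone as scaling. The count was 1586 with the number run as covariate, 1423 without the 4 libraries numbered 12 to 18 and 1446 with only these 6 libraries fitted. It was 450 without day 0 replicate 1 and 465, 520 and 516 without day 6 replicates 1, 2 and 3.

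On day 9, cell cycle genes were lower than on day 0 in 18 of 45 and higher in none (40 adjusted over the list alone), with the transcription factor gene Tcf19, outside that list, at -1.99 ± 0.36 log2 (SE, n = 3 per group, adjusted p = 0.00361). The set test of the cell cycle list passed (adjusted p = 8.56e-48, and adjusted p = 0.151 with an estimated correlation). The growth factor receptor Csf1r was higher by 0.87 ± 0.12 (adjusted p = 0.00045), Ass1 by 2.72 ± 0.38 (adjusted p = 0.00045) and Gbp3 by 1.25 ± 0.23 (adjusted p = 0.00332), whereas the chemokine Cxcl10 was lower at -2.79 ± 0.46 (adjusted p = 0.00203). Mmp14 was higher by 5.48 ± 0.62 (adjusted p = 4.92e-05), by 6.20 without day 0 replicate 1 and by 4.66 without day 9 replicate 2. Its call was lost when only these 6 libraries were fitted (0.0554, in a range of 1.47e-18 to 0.0554 over the alternatives). None of the 30 resident identity genes was called by edgeR (0 adjusted over the list alone, 2 at an unadjusted p under 0.05 and 0 by DESeq2). In total 474 genes changed, 219 up and 255 down, and 175 up and 457 down with library size alone as scaling. The count was 1076 with the number run as covariate, 818 with DESeq2 and 122 with only these 6 libraries fitted. It was 167 and 307 without day 0 replicates 1 and 3, and 294 and 216 without day 9 replicates 1 and 3.

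On day 12, a small set of genes stayed apart from the untreated level. Mmp14 was higher by 5.08 ± 0.61 log2 (SE, n = 3 per group, adjusted p = 7.68e-05), by 5.80 without day 0 replicate 1 and by 4.23 without day 12 replicate 1. Ass1 was higher by 2.72 ± 0.38 (adjusted p = 0.000337), and Csf1r by 0.71 ± 0.12 (adjusted p = 0.00258), while Gbp3 was 2.83-fold higher (adjusted p = 0.000688). The calcium binding gene S100a6 was higher by 3.23 ± 0.32 (adjusted p = 3.84e-06), and 3 of 20 monocyte genes were higher and none lower (4 adjusted over the list alone), among them F13a1 at 5.99 ± 1.04 (adjusted p = 0.00349). Of 45 cell cycle genes, 1 was lower and none higher (5 adjusted over the list alone), and none of the 30 resident identity genes was called by edgeR (0 adjusted over the list alone, 0 at an unadjusted p under 0.05 and 0 by DESeq2). In total 177 genes changed, 149 up and 28 down, and 124 up and 69 down with library size alone as scaling. The count was 379 with the number run as covariate and 389 with DESeq2. It was 108, 112 and 93 without day 0 replicates 1, 2 and 3, and 75 and 111 without day 12 replicates 1 and 3. A joint test of all days against day 0 called 3554 genes, 5283 with the number run as covariate and 2106 without day 3 replicate 3, and adjusted over the list alone it called 29 of 29 interferon-stimulated, 45 of 45 cell cycle, 25 of 29 inflammatory and 1 of 30 resident identity genes.

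**Figure D3:**
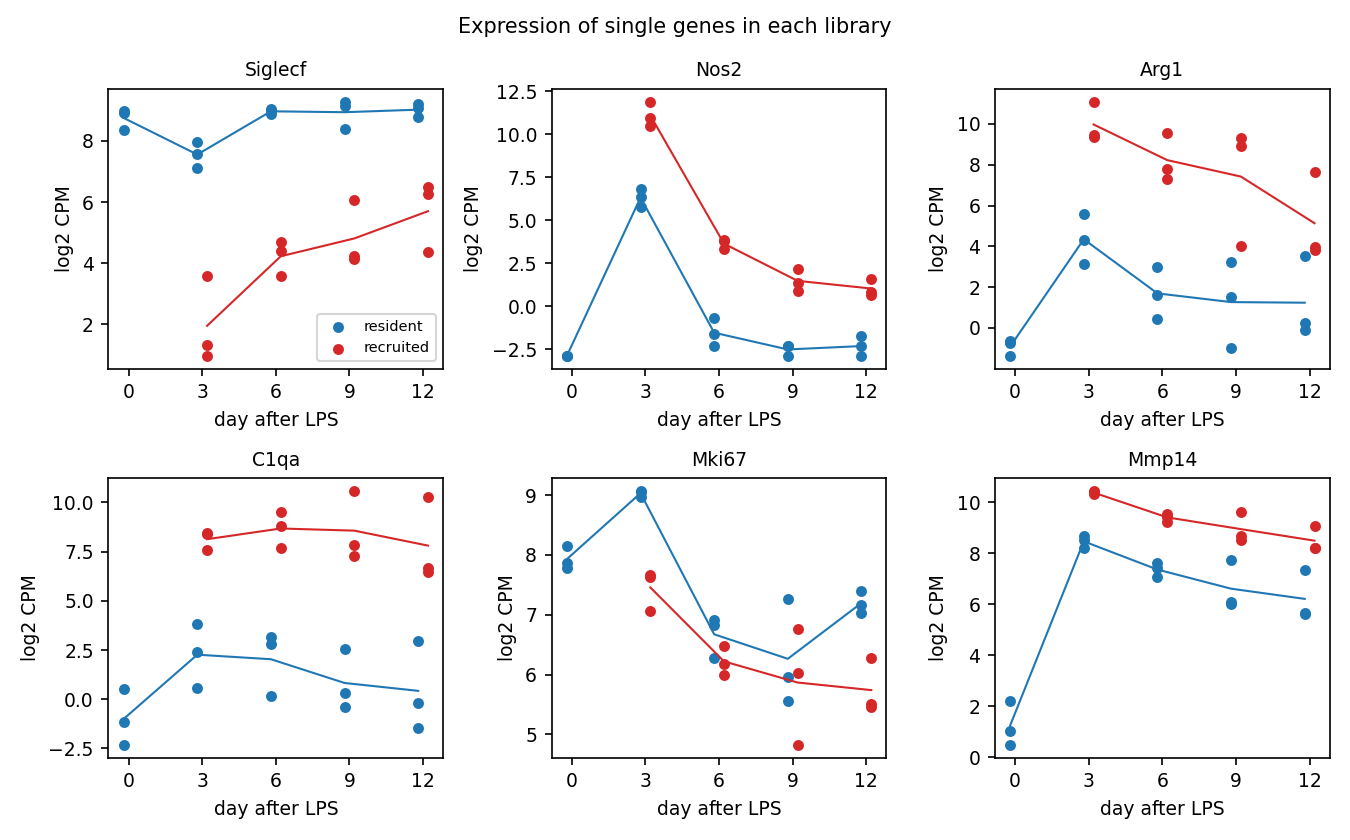
Log2 CPM of 6 genes against the day after LPS, 1 point per library and a line through the group means, resident in blue and recruited in red. Mmp14 of resident cells rose from 2.58 to 359 CPM on day 3 and was 164, 49.7 and 49.9 CPM in replicates 1, 2 and 3 of day 12, and Nos2 was highest on day 3 in both populations.

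The change of recruited cells with time was measured against their own day 3. On day 6, interferon-stimulated genes fell in 29 of 29 (29 adjusted over the list alone), with Isg15, an antiviral ubiquitin-like protein, going from 226 ± 45.9 to 6.21 ± 1.83 CPM (SD, n = 3), a change of -5.17 ± 0.54 log2 (SE). Inflammatory mediators fell in 21 of 29 and rose in 1, Tgfb1 at 0.43 (22 adjusted over the list alone), with Cxcl10 at -7.16 ± 0.44 (adjusted p = 3.51e-10) and Tnf at -4.10 ± 0.69. Nos2 changed by -7.58 ± 0.47 (adjusted p = 1.31e-09). The set tests of the interferon (adjusted p = 7.51e-33), inflammatory (adjusted p = 2.51e-13) and arginine lists (adjusted p = 0.00132) passed, and held at adjusted p = 0.0386, 0.0217 and 0.0319 with an estimated correlation. Glycolysis genes fell in 17 of 22 and rose in 1, Pfkfb4 at 1.04 (18 adjusted over the list alone), oxidative phosphorylation genes fell in 24 of 45 and rose in none (25 adjusted over the list alone), and neutrophil markers fell in 11 of 14 (11 adjusted over the list alone). Resident identity genes rose in 12 of 30 and fell in 1, Tgm2 at -1.28 (13 adjusted over the list alone), with the mannose receptor Mrc1 at 2.60 ± 0.41 (3.40 without day 3 replicate 1), and Pros1, a bridge to dying cells, rose by 2.23 ± 0.19. In total 4332 genes changed, 2051 up and 2281 down, and 2341 up and 1739 down with library size alone as scaling. The count was 5319 with the number run as covariate.

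On day 9, resident identity genes were above day 3 in 15 of 30 and below in 1, Tgm2 at -1.16 (17 adjusted over the list alone), with Mrc1 at 3.55 ± 0.43 log2 (SE, n = 3 per group, adjusted p = 1.45e-06) and at 4.36 without day 3 replicate 1. The epoxide hydrolase Ephx1 was higher by 6.14 ± 0.49 (adjusted p = 4.14e-09) and Pros1 by 3.06 ± 0.19. The monocyte gene Plac8 was lower at -9.01 ± 0.59 (adjusted p = 3.63e-10) and Nos2 at -9.67 ± 0.52 (adjusted p = 1.22e-10). All 29 of 29 interferon-stimulated genes were lower (29 adjusted over the list alone), as were 23 of 29 inflammatory mediators with 1 higher, Tgfb1 at 0.37 (25 adjusted over the list alone). The set tests of the interferon (adjusted p = 3.53e-32), inflammatory (adjusted p = 4.57e-14) and arginine lists (adjusted p = 0.000999) passed, and held at adjusted p = 0.0386, 0.0166 and 0.0364 with an estimated correlation. Cholesterol synthesis genes were higher in 6 of 22 and lower in none (6 adjusted over the list alone). Epithelial markers were higher in 5 of 11, among them Epcam at 1.86 (5 adjusted over the list alone), and erythroid markers in 4 of 4 (4 adjusted over the list alone), with the globin gene Hbb-bs at 97.6 CPM in replicate 3, 4.73 in replicate 2 and 0 in replicate 1. The surfactant gene Sftpb, among the epithelial markers, lost its call without recruited day 9 replicate 2 (0.168) and without day 3 replicates 2 and 3 (0.0523 and 0.0538), in a range of 0.00353 to 0.168 over the alternatives. In total 4933 genes changed, 2479 up and 2454 down, 3044 up and 1787 down with library size alone as scaling and the median of all genes moved by 0.12. The count was 5935 with the number run as covariate and 2772 with only these 6 libraries fitted.

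On day 12, resident identity genes were above day 3 in 22 of 30 and below in 1, Tgm2 at -0.90 (24 adjusted over the list alone). Siglecf went from 5.31 ± 5.59 to 61.9 ± 36.5 CPM (SD, n = 3), a rise of 3.53 ± 0.66 log2 (SE, adjusted p = 0.000242), Pparg from 18.4 ± 6.82 to 96.7 ± 28.1 CPM (SD, adjusted p = 1e-05), and Mrc1 rose by 4.16 ± 0.44 (adjusted p = 1.86e-07). Without day 3 replicate 1 Siglecf rose by 4.89 and Mrc1 by 4.97. Ephx1 rose by 6.81 ± 0.49 (adjusted p = 7.24e-10). Cholesterol synthesis genes rose in 14 of 22 and fell in none (14 adjusted over the list alone), with Cyp51, which removes a sterol methyl group, at 2.23 ± 0.47, and fatty acid oxidation genes rose in 12 of 25 and fell in 3, Slc25a20, Acaa1a and Acsl1 (15 adjusted over the list alone). Glycolysis genes fell in 18 of 22 and rose in 2, Pfkfb4 (1.82) and Aldoc (1.49) (20 adjusted over the list alone). Inflammatory mediators fell in 21 of 29 and rose in 2, Ccl22 (1.78) and Tgfb1 (0.48) (24 adjusted over the list alone), and their set test passed (adjusted p = 1.42e-11, and adjusted p = 0.0406 with an estimated correlation). Nos2 changed by -10.18 ± 0.53 (adjusted p = 7.45e-11), and Ly6c2 by -5.84 ± 0.66. Mki67 fell by 1.70 ± 0.40 (adjusted p = 0.00217), while of 45 cell cycle genes 2 were higher, among them Mcm7 at 0.92 ± 0.18, and 2 lower, among them Mki67 (2 adjusted over the list alone). Monocyte-derived macrophage genes were higher in 7 of 24 and lower in 6 (13 adjusted over the list alone), with a median of 0.64 and a mean of 0.14 against a set test that pointed down (adjusted p = 0.889). In total 5348 genes changed, 2698 up and 2650 down, and 3046 up and 2084 down with library size alone as scaling. The count was 6362 with the number run as covariate. The joint test of days 6, 9 and 12 against day 3 called 5105 genes, 6492 with the number run as covariate, and adjusted over the list alone it called 29 of 29 interferon-stimulated, 22 of 30 resident identity and 2 of 45 cell cycle genes.

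**Figure D4:**
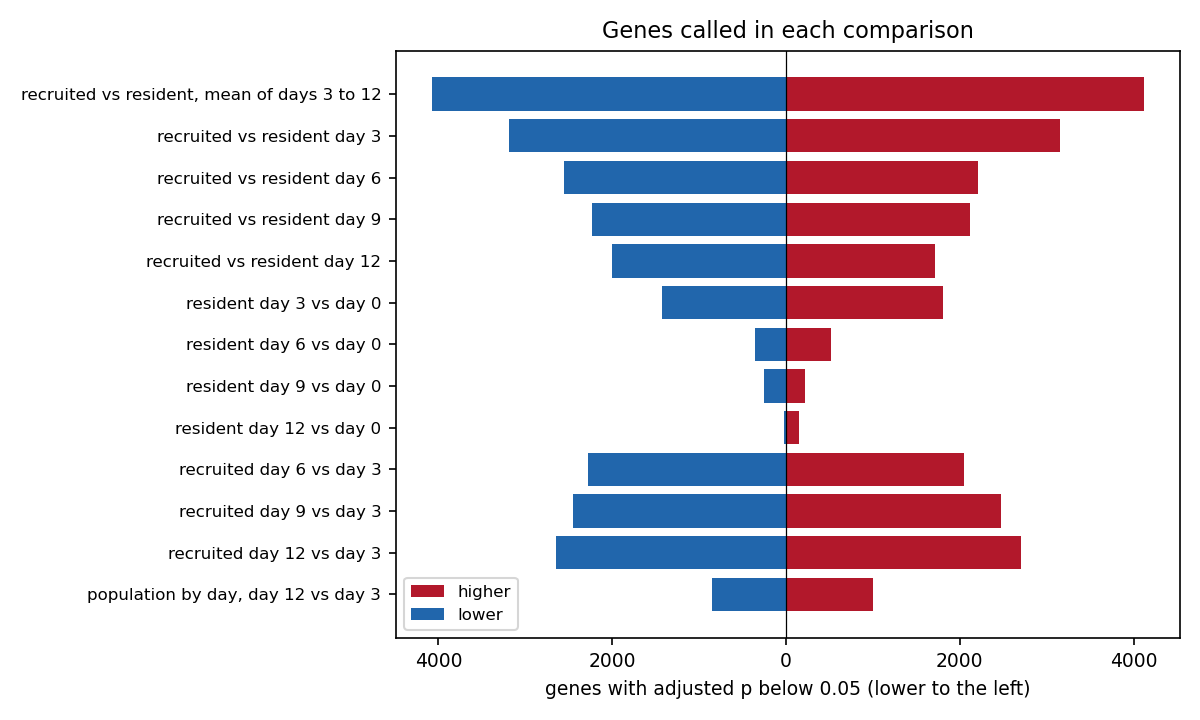
Number of genes with adjusted p below 0.05 in each comparison, higher to the right and lower to the left of 0. The populations differed in 6342 genes on day 3 and 3713 on day 12, and resident cells differed from day 0 in 3232 genes on day 3 and 177 on day 12.

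Whether the difference between the populations itself changed with time was tested as an interaction. From day 3 to day 12, the recruited minus resident difference moved up in 11 of 30 resident identity genes and down in none (15 adjusted over the list alone), with Mrc1 at 3.83 ± 0.56 log2 (SE, n = 3 per group, adjusted p = 0.000151, and 4.63 log2 without recruited day 3 replicate 1) and Pparg at 2.25 ± 0.46 (adjusted p = 0.00243). Siglecf did not pass (2.09 ± 0.84, adjusted p = 0.11) except without recruited day 3 replicate 1 (0.00932) or day 12 replicate 1 (0.0401), in a range of 0.00932 to 0.241 over the alternatives. Cell cycle genes moved up in 17 of 45 and down in none (26 adjusted over the list alone), with the thymidylate enzyme Tyms at 2.04 ± 0.28 (adjusted p = 6.06e-05). The mean score of that list went from 5.97 to 4.52 log2 CPM in resident cells and from 2.65 to 2.84 in recruited cells. Its narrower gap thus came mostly with a fall in resident cells. Interferon-stimulated genes moved down in 16 of 29 and up in none (21 adjusted over the list alone), and glycolysis genes down in 10 of 22 and up in 1, Pfkfb4 at 1.01 (15 adjusted over the list alone), with the glycolytic regulator Pfkfb3 at -1.48 ± 0.18. Inflammatory mediators moved both ways, up in 3 of 29, Ccl9, Ccl17 and Csf1, and down in 4, Il1b, Il27, Cxcl10 and Il1rn (7 adjusted over the list alone). The call of Il1b (adjusted p = 0.0316) was lost under 12 alternatives, among them leaving out any 1 of the resident day 3 libraries, in a range of 0.0124 to 0.189. Their set test did not pass (adjusted p = 0.2, 0.394 with the block, and 0.727 and 0.735 with an estimated correlation without and with it). On days 6, 9 and 12 themselves the list was higher in recruited cells in 11, 7 and 8 of 29 and lower in 3, 2 and 1 (16, 9 and 9 adjusted over the list alone). Csf1 moved up by 3.44 ± 0.50 (adjusted p = 0.000141), with resident cells going from 25.5 ± 10.2 to 1.49 ± 0.333 CPM (SD, n = 3) and recruited cells from 67.6 ± 24.4 to 42.8 ± 3.27. Antigen presentation genes moved down in 6 of 17 and apoptosis genes in 10 of 30, with none up in either list (7 and 11 adjusted over the list alone), and the death inducer Bcl2l11 was at -1.38 ± 0.14 (adjusted p = 1.05e-05). With the block, the set test of monocyte-derived macrophage genes passed with the preset correlation (0.298 to 0.0398) but not with an estimated one (0.429).

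In total the difference between day 12 and day 3 was called for 1853 genes, 1004 up and 849 down, and the split was 1204 to 479 with library size alone as scaling, which moved the median of all genes by 0.119. The count was 2819 with the number run as covariate and 2946 with the block of library pairs. Over any day against day 3, 1449 genes were called, 2483 with the number run as covariate, 2472 with the block and 2222 without the 4 libraries numbered 12 to 18. The count was 897 and 939 without recruited day 3 replicates 2 and 3. Adjusted over the list alone, the joint test called 36 of 45 cell cycle and 23 of 29 interferon-stimulated genes.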

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

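Of the tests weighed here, those on a batch shared by the libraries numbered 12 to 18, on a change of recruited cells with time, on recruited cells or neutrophils in the resident day 3 gate and on Nos2 were chosen only after the result was seen.

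Differences between the populations that changed with time were listed because an interaction test showed them: 1449 genes over any day and 1853 between days 12 and 3. The recruited minus resident difference moved up most in Cspg4 (5.84 log2), Ephx1 (5.59), Gprc5c (4.67), Thbs1 (4.40) and H2-M2 (4.30), and down most in Spon1 (-5.85), Plekhg4 (-4.12), Ifit1bl1 (-4.08), Cxcr2 (-3.67) and Timp1 (-3.51). Calls of Ephx1, Gprc5c, H2-M2, Spon1 and Ifit1bl1 held under every alternative run. The other 5 were lost under some, with the highest adjusted p at 0.279 for Cspg4 (without recruited day 12 replicate 1), 0.0676 for Thbs1 (without resident day 12 replicate 3), 0.152 for Plekhg4 (without resident day 12 replicate 2), and 0.0671 for Cxcr2 and 0.501 for Timp1 (both without resident day 12 replicate 1).

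Chance was examined by regrouping the same libraries. Comparisons of 3 against 3 libraries and the interaction of day 12 against day 3 allow 10 splits, too few for a share under 0.05. Only 1 split, the real one, gave as many genes in each of them, and the highest other counts were 0 against 6342, 4758, 3713 and 1853 (populations on days 3, 6 and 12 and the interaction), 9 against 4350 (populations on day 9), 1 against 3232 and 0 against 873, 474 and 177 (resident days 3, 6, 9 and 12), and 1, 35 and 10 against 4332, 4933 and 5348 (recruited days 6, 9 and 12). On day 9 the splits that part all pairs as the real one does called 0. Splits other than the real one put real differences between groups into the spread within groups, which lowers their counts. Where 100 splits were counted, 99 of them drawn, only the real one was as large, which argues against chance without excluding it. This holds for the average over days (8198 against 6104, with labels swapped within the 12 pairs), resident cells on any day (3554 against 430), recruited cells on any day (5105 against 2683) and the interaction over any day (1449 against 1045, with pairs moved whole).

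Reads outside genes were listed because their share lay above the highest untreated library (11.19%) in 9 libraries: resident day 6 replicate 1 (11.83%) and day 9 replicate 1 (12.66%), and recruited day 3 replicates 1 and 2 (11.95% and 11.22%), day 6 replicates 1 and 2 (12.31% and 26.45%), day 9 replicates 1 and 3 (13.02% and 12.14%) and day 12 replicate 2 (11.29%). The cause was not tested.

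The 4 libraries numbered 12 to 18, replicate 2 of day 9 and replicate 1 of day 12 in both populations, deviated from their groups alike. A batch shared by them may be the source, since the deviations correlated at 0.37 or more over 3111 genes. These were called neither between the populations, averaged or on single days, nor in the joint tests of resident or recruited days. For other day 9 and 12 libraries the correlations were -0.08 to 0.08. Their groups held only 2 such libraries each, whose deviations mirror each other, so only the size of these values counts. The 3111 genes were picked from fits that held the 4 libraries. Argued against is a bias by transcript length, with rank correlations from -0.04 to 0.12 and the smallest in size at 0.01, in differing directions. One of these missed the bound of 0.1 written before the result was seen, and the reading was then changed to the differing directions. A slower resolution of injury in these animals cannot be told apart from a batch, since the deviation followed the early response at 0.34, 0.17, 0.18 and -0.03 in the 4 libraries.

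Resident identity genes were higher in recruited cells on day 12 than on day 3. Resident cells carried over into the recruited gate would raise these genes by like shares of the gap between recruited day 3 and resident day 12 cells, but the upper quartile of the shares was 3.3 times the lower over 21 of the 22 raised genes (12.6% to 41.5%, median 24.3%). The other, Gpnmb, was lower in resident day 12 than in recruited day 3 cells, so carry-over would lower it. Shares of the gap ran from 6.63% for Perp to 187% ± 26.4 (SD, n = 3) for Cd200r4 and 251% ± 51.8 for Bhlhe40. Small gaps inflate the latter pair, whose levels were 217.5 and 368.6 CPM against 146.1 and 292.8 in resident cells, not called between the populations on day 12 (adjusted p = 0.0687 and 0.13), so they add little. The spread of the quartiles argues against carry-over as the whole cause, while carry-over up to about the lowest shares stays open. A change of the recruited cells with time stays open beside such a part. Over all 27 genes of the list at least 2 times higher in resident cells, called or not, the lowest day 12 library (5.33%) lay 1.37 points above the highest day 6 library (3.96%), less than the SD of 7.24 points between day 12 libraries. Replicates 1, 2 and 3 were at 5.33%, 18.4% and 17.2% on day 12 and at 1.44%, 2.23% and 14.6% on day 9. Day 12 replicate 1 and day 9 replicate 2 belong to the libraries numbered 12 to 18. A gate that differed between days was not tested, and Itgax transcripts rose in recruited cells over the same days.

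Resident cells on day 3 had more Itgam and neutrophil marker transcripts than untreated ones. For recruited cells in the resident gate, rises were taken as shares of the gap between day 0 and recruited day 3 cells. Over 280 genes far higher in recruited cells, the shares were unlike (upper quartile 4.5 times the lower). These genes include inflammatory and interferon genes such as Cxcl3 (95.1%) and Gbp2 (48.2%), which resident cells may raise themselves. Unlike shares would then arise with or without carry-over, so they decide nothing for Itgam or the neutrophil markers. A few neutrophils cannot be told apart from a response of the resident cells, since S100a8 and S100a9 rose from 3.32 to 59.6 and from 0.133 to 46.4 CPM. Their rise was at most 0.0841 of that of Lcn2, which sets Lcn2 apart from them but decides nothing for the other markers. Monocyte and complement genes rose by low shares of this gap (Ly6c2 3.44%, Plac8 3.16%, C1qa 2.18%, Ccr2 1.95%, F13a1 1.69%), and carry-over of that size stays open for them. Itgam stood higher, at 11.4%, 10.7% and 16.8% in replicates 1, 2 and 3. The median share of C1qa, C1qb, C1qc and Ccr2 was 4.42%, 0.423% and 1.53%. Itgam was thus at 2.59, 25.2 and 11 times that share. A very small share inflates the ratio of replicate 2, where C1qa was at 1.33 CPM. Carry-over alone would raise Itgam by a share like that of these 4 genes. Its higher share in all 3 libraries argues against carry-over as the whole cause for Itgam. For Nos2, carry-over cannot be told apart from expression by resident cells, because its share was 1.09, 5.51 and 2.19 times that of the same 4 genes. A response of the resident cells stays open for each of these genes.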

How the results depend on the processing

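The fits with the number run, without the 4 libraries numbered 12 to 18 and without the day 6 pair, and set tests with both the block and an estimated correlation, were chosen only after the result was seen. No named gene changed its direction between values of which at least 1 was called. The larger of the up and down counts changed side under at least 1 alternative in each comparison except the populations on day 6, resident day 12 and the interaction of day 12. With library size alone it did so for the populations on average (3741 up and 4165 down) and on day 9 (2170 and 1900), for resident days 3 (1427 and 1626) and 6 (371 and 630) and for recruited day 6 (2341 and 1739). Some score differences that no test had called changed sign with a prior count of 0.5, as for the epithelial list on resident day 6 (-0.14 to 0.2), and the uncalled epithelial set test between the populations turned from down to up with the block (adjusted p = 0.824 and 0.508). Of 153 counts of called genes, called sets and separated scores recomputed with another setting, 137 stayed within 1.5 times the reported count, as did 136 of 153 gene counts with a library left out. Of 11389 recomputed changes of named genes 10980 kept their call, 363 lost and 46 gained it, and with a library left out 8528 of 9384 kept, 846 lost and 10 gained it. List counts stayed within 1.5 times in 3645 of 4200, and score differences moved by less than the spread in 286 of 308. Set tests were the least stable: of 912 recomputed, 647 kept their call, 221 lost and 44 gained it. Exceptions named within a list were followed only through its count. Depth limits genes near the floor, such as Nos2 in resident cells outside day 3.

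Counts that moved further were these, and the cause was not tested. With the number run, resident days 6, 9 and 12 against day 0 gave 1586, 1076 and 379, and the interactions 2483 (any day) and 2819 (day 12). Without the 4 libraries numbered 12 to 18, resident day 6 gave 1423 and the interaction over any day 2222. With only the compared libraries, fewer samples set the spread, and the populations on day 9 gave 2497, resident days 6 and 9 gave 1446 and 122, and recruited day 9 gave 2772. DESeq2 gave 818 and 389 for resident days 9 and 12. The replicate block within days gave 2472 and 2946 for the interactions, and its other counts stayed within 1.5 times. Camera with an estimated correlation called 8 sets, against 140 with the preset one and 146 by fry. Of 144 set tests with the block it called 78 with the preset correlation and 1 with an estimated one, monocyte-derived macrophage genes between the populations on day 9 (adjusted p = 0.0392, against 4.6e-07 without the block and with the preset correlation).

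With single libraries left out, counts ranged from 2106 to 3773 for resident cells on any day, 1895 to 2850 for resident day 3, 450 to 605 for day 6, 167 to 405 for day 9 and 75 to 144 for day 12, and from 897 to 1679 for the interaction over any day. Across days, replicate numbers did not pair the libraries (r from -0.15 to 0.23), and a replicate block over all days gave 3246, 870, 469 and 181 for resident days 3 to 12 and 4331, 4966 and 5366 for recruited days 6 to 12.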

Other observations

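The values here were looked up only after the result was seen, except the list counts.

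Some red cell and epithelial transcripts stood out in single libraries. Hbb-bs, a globin gene, was at 97.6 CPM in recruited day 9 replicate 3 and at 73.7 CPM in resident day 9 replicate 3, and at 4.73 and 4.64 CPM in replicate 2 of that day. Every other library had at most 2.43 CPM. The surfactant gene Sftpc was highest in recruited day 9 replicate 2 (13.5 CPM) and day 12 replicate 1 (12 CPM), which belong to the libraries numbered 12 to 18. Of 11 tested epithelial markers, Ager, Cldn18, Krt8, Sftpa1, Sftpb and Sftpc were highest in the library numbered 12 to 18 in 4 of 4 groups that held one, Foxj1 in 3 of 4, Scgb1a1 in 1 of 4, and Epcam, Cdh1 and Bpifa1 in 0 of 4.

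In resident cells, 6 of 16 tested T and NK cell markers rose on day 3 and 7 of 16 on day 6. On days 9 and 12 edgeR called 0 and 0 of 16 (1 and 5 at an unadjusted p under 0.05, and 0 and 1 by DESeq2). Cd8a, a T cell coreceptor, had no count on day 0 and was at least 6.73-fold higher on day 3 and at least 15.7-fold higher on day 6, and the T cell receptor gene Trbc2 was at least 10.5-fold higher on day 6. Lck, a T cell kinase, was at 3.2 CPM in resident day 6 replicate 1 and at 0.848 and 0.645 CPM in replicates 2 and 3.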
